A study of Mus musculus with 12 samples.

How the data were processed

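Total RNA from C2C12 mouse myoblasts was sequenced from stranded libraries in 4 groups of 3, which crossed an siRNA against Crebl2 or Renilla luciferase (Luc) with rapamycin or ethanol. One siRNA sequence against Crebl2 was used in these libraries, per the labels. The deposited values were whole-number read counts for 58611 Ensembl transcripts in each of the 12 libraries, with no normalization. Trim Galore, TopHat and HTSeq are named in the submitters' processing notes, without versions or settings. Those notes name both mm9 and GRCm38 as genome builds, and the annotation release, the strand setting and the rule for reads that several transcripts share were not given in the sources used here.

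Gene names and coordinates came from GENCODE M21 on GRCm38, to which 99.41% of the transcript identifiers matched (58264), 91.8% of these with the same version number. The other 347 identifiers held 0.038% of the reads and were left out. Test designs fixed before the data were examined had assumed counts per gene, so transcript counts were summed over the listed transcripts of each gene, which gave 38481 genes, 27866 of them with 1 listed transcript. Of 8507 protein-coding transcripts with no exonic base of their own, 99.3% had no read in any library, against 32.0% of 31837 transcripts with such bases. Reads that overlap several listed transcripts are therefore missing from the counts. For each gene the share of exonic bases belonging to a single listed transcript was computed and is called its countable share. It was below 10% for 2791 and above 90% for 11808 of 21782 protein-coding genes, and Gapdh, Ldha, Txnip and Asns had almost no counts. The 37 listed mitochondrial transcripts had no reads. Without a stated strand setting, genes that overlap an antisense neighbour remain uncertain: 35 protein-coding genes were free on their own strand and covered on the other, and 3 of these reached a mean count of 10. Totals ranged from 33404087 to 42891015 counts per library.

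Genes were kept with the edgeR filter by group at a minimum count of 10, which left 13247 genes. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a mean for each of the 4 groups and all 12 libraries in one fit. Common biological variation was 6.9%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The 5 contrasts were the Crebl2 siRNA against the Luc siRNA in ethanol and in rapamycin, rapamycin against ethanol with each siRNA, and the interaction, which is the rapamycin change with the Crebl2 siRNA minus that with the Luc siRNA. Standard errors were the log2 fold change divided by the square root of F. Levels are given in CPM, the usual read-count rate of edgeR, after TMM scaling.

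In the same way, 37 gene lists were fixed in advance for metabolic pathways, stress and growth programmes, muscle and other cell-type markers. The 31 lists with at least 5 tested members were compared with all other tested genes by limma's camera (limma 3.58.1, voom values, preset correlation of 0.01), adjusted over the lists within a contrast. Members were counted from the edgeR calls over all genes and again adjusted over the list alone. Camera with an estimated correlation and limma's fry were alternatives.

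Named genes followed a fixed rule: Crebl2; the 8 largest rises and 8 largest falls in the first siRNA and the first rapamycin contrast and 4 each way in the others, among called protein-coding genes with a mean of at least 5 CPM, no overlap between the 6 libraries compared (not required for the interaction) and a symbol that is not a predicted gene. The 3 members with the smallest p of each called list and 2 of other lists were added. Any other gene is named as such, and 2 genes that the rule picked are not reported here.

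The edgeR fit was tested on simulated counts for 13247 genes with known changes. It recovered 63.3% of 2-fold changes for the Crebl2 siRNA in ethanol, 78.0% for rapamycin with the Luc siRNA, 62.5% for the Crebl2 siRNA in rapamycin, 79.2% for rapamycin with the Crebl2 siRNA and 60.0% for the interaction. False calls made up 3.15%, 8.57%, 4.96%, 5.11% and 7.55% of the calls in the same order. For each contrast and fold size, 48 to 50 of the tested genes had been changed. The pairwise contrasts called far more genes, so these shares belong to the simulated setting. Alternatives were RLE scaling, DESeq2 1.42.0, no count filter, a minimum count of 50, a replicate block, a fit of only the compared groups, protein-coding nuclear genes only, and leaving out each library in turn. Transcripts tested one by one and genes with at least 90% countable bases were added after the data had been seen. Similarity between contrasts that share libraries was set beside 20 simulations of unchanged groups. All 7-base words in the 3' UTRs of 8849 genes were tested by regression of log2 fold changes on word presence, UTR length, GC content and expression, to look for matches of the siRNA. This search, the random draws and the plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.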

Results

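RNA was profiled in C2C12 cells, a mouse myoblast line that can form muscle fibres. Cells carried an siRNA against Crebl2, a bZIP-domain protein related to CREB, or a control siRNA against Renilla luciferase (Luc) for 3 days and then received 20 nM rapamycin, an inhibitor of the mTOR kinase, or ethanol for 12 hours. Each of the 4 groups held 3 libraries. Library totals were 39080581, 40016235 and 35115590 counts for the Luc siRNA in ethanol and 35341291, 39745107 and 35538507 counts for the Luc siRNA in rapamycin. With the Crebl2 siRNA they were 40421317, 33404087 and 42891015 counts in ethanol and 38573637, 36104338 and 34206710 counts in rapamycin. The first principal component carried 41.6% of the variance and separated rapamycin (5.39 to 41.62) from ethanol (−42.79 to −5.06). The second carried 26.3% and separated the Luc siRNA (5.84 to 34.56) from the Crebl2 siRNA (−33.57 to −5.6). Each component also separated the other factor. On the first, the Luc siRNA lay at −12.09 to −5.06 in ethanol and 34.86 to 41.62 in rapamycin. The Crebl2 siRNA lay at −42.79 to −39.54 and 5.39 to 13.88 there. On the second, rapamycin lay below ethanol with the Luc siRNA (5.84 to 7.86 against 27.65 to 34.56) and the Crebl2 siRNA (−33.57 to −28.45 against −9.82 to −5.6). None of the sources used here says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Reads shared between listed transcripts are missing from the counts, so changes of genes with a low countable share rest on part of their bases. This share was 19.9% for Tef, 32.8% for Psat1, 34.9% for Bgn, 37.5% for Acat2 and 47.4% for Cdkn1b. It lay between 54.4% and 89.7% for Mcm7, Nop56, Tubb3, Elovl6, Tpi1, Cdkn1a, Pik3ip1, Ube2c, Vcam1, Sesn3, Cenpa and Ndufb2. Values in parentheses after a gene are log2 fold changes unless stated otherwise, and ± gives the SD of 3 libraries.

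Crebl2, the targeted gene, was lower in every library with its siRNA. It stood at 23.81, 25.3 and 26.18 CPM with the Luc siRNA in ethanol and at 4.87, 7.41 and 6.02 CPM with the Crebl2 siRNA. In rapamycin it stood at 39.96, 36.41 and 36.28 CPM with the Luc siRNA and at 10.65, 8.97 and 9.49 CPM with the Crebl2 siRNA. The mean was 75.7% lower in ethanol (log2 fold change −2.05, SE 0.11, edgeR adjusted p = 3.7e-09) and 74.2% lower in rapamycin (−1.95, SE 0.11, edgeR adjusted p = 3.6e-09). Rapamycin raised Crebl2 itself 1.5-fold with the Luc siRNA (0.58, SE 0.1, edgeR adjusted p = 0.00019) and 1.6-fold with the Crebl2 siRNA (0.68, SE 0.12, edgeR adjusted p = 2e-04). These rises were not called different by the interaction term (0.10, SE 0.15, edgeR adjusted p = 0.84). The 2-sided exact permutation p was 0.1 in all 4 contrasts, the smallest that 3 libraries against 3 allow. Crebl2 lies on the plus strand of chromosome 6 at 134830154 to 134858931 (GRCm38). Of its exonic bases, 83.1% were countable.

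The first question was what the loss of Crebl2 changes without rapamycin. Actc1, the cardiac alpha-actin also made by young muscle, went from 72.6 ± 9.84 to 6.27 ± 0.182 CPM, an 11.6-fold fall (−3.53, SE 0.12, edgeR adjusted p = 1.5e-10). Myog, the transcription factor myogenin that drives muscle differentiation, went from 203 ± 22.5 to 20.1 ± 4.19 CPM, a 10.1-fold fall (−3.33, SE 0.15, edgeR adjusted p = 7.4e-10). Acta1, the skeletal alpha-actin, fell 8.01-fold from 287 ± 45.4 to 35.8 ± 3.38 CPM. Neurofilament light chain, Nefl, rose 5.55-fold from 53.3 ± 4.66 to 296 ± 6.92 CPM (2.47, SE 0.10, edgeR adjusted p = 1.5e-10).

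In all, 2836 genes rose and 2246 fell, or 38.4% of the 13247 tested, and 223 rose and 387 fell at least 2-fold. The other large falls were in Hfe2 (−3.0, SE 0.17), a BMP co-receptor of muscle, Ifi27l2a (−2.77, SE 0.17), an interferon-inducible gene, and Mymk (−2.35, SE 0.13), the fusion protein myomaker of which 28.5% of bases were countable. Next came Klhl41 (−2.30, SE 0.14), which stabilises sarcomere proteins, and Trdn (−2.17, SE 0.14), the calcium-release protein triadin. The other large rises were in Stc1 (2.39, SE 0.20), a secreted glycoprotein, Nefm (2.22, SE 0.13; 78.7% countable), the medium neurofilament chain, Sprr1a (2.16, SE 0.09), a cornified-envelope protein, and Pappa (2.07, SE 0.12), a protease of IGF-binding proteins. Acsbg1 (1.97, SE 0.12), an acyl-CoA synthetase, Areg (1.91, SE 0.12), an EGF receptor ligand, and Tnc (1.87, SE 0.15; 12.1% countable), a matrix glycoprotein, followed. Myog, Actc1 and Nefl lie on chromosomes 1 (134289989 to 134292548), 2 (114047282 to 114053548) and 14 (68083863 to 68089095).

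**Figure D1:**
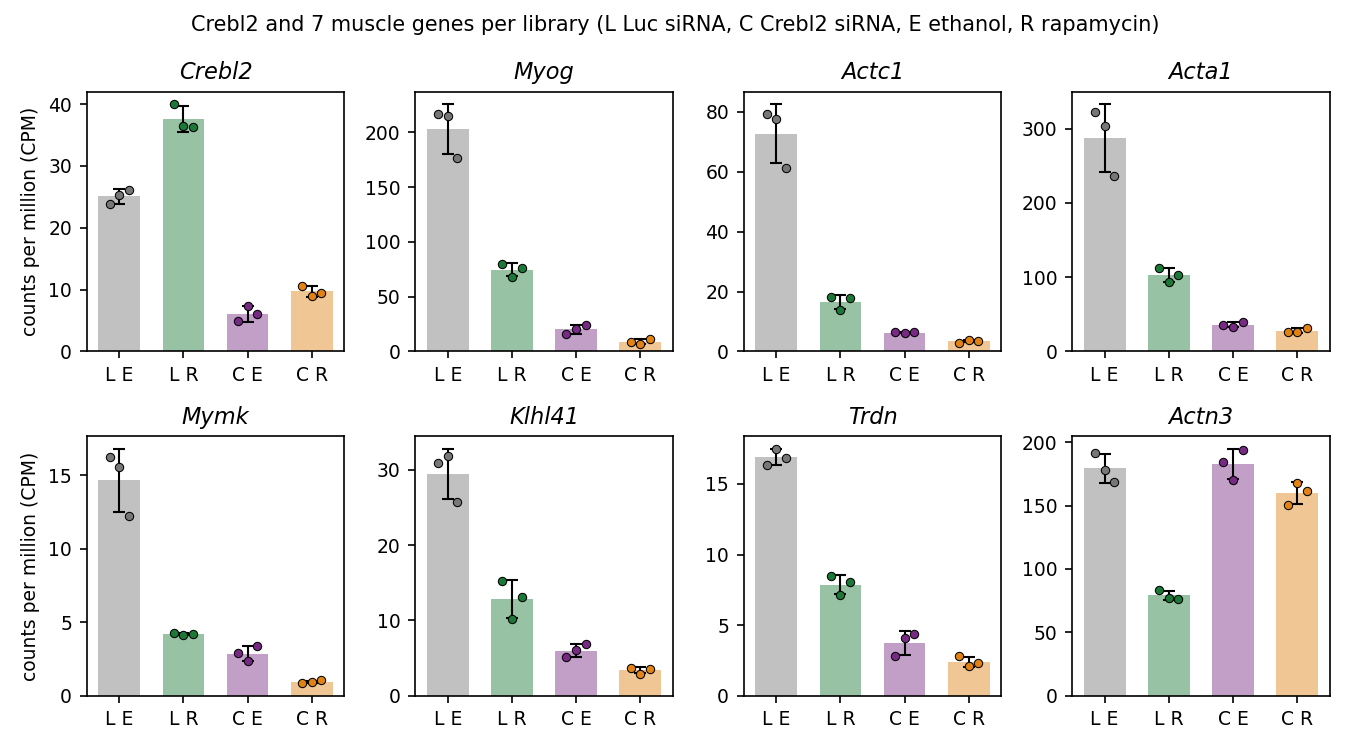
Scaled read counts (CPM, vertical axis) of Crebl2 and 7 muscle genes in the 4 groups; bars are means, error bars are the SD and points are the 3 libraries of each group. Myog fell from 203 to 20.1 CPM with the Crebl2 siRNA in ethanol, while Actn3 stood at 79.1 CPM with the Luc siRNA and 160 CPM with the Crebl2 siRNA in rapamycin.

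In the muscle differentiation list, 16 of the 21 tested members fell and 5 did not pass, with a median log2 fold change of −2.23 (camera adjusted p = 1e-12, adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, 16 fell and 1 rose. Besides Actc1, Acta1 and Myog, Myom2 (−2.12), an M-band protein, fell. Of the 16 that fell, 6.2% carried the 7-base word GAAATGT, which occurs in the Crebl2 transcript, in their 3' UTR.

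Growth-related lists rose. Of 53 ribosome biogenesis genes, 46 rose and 7 did not pass (47 rose adjusted over the list alone, camera adjusted p = 6.1e-20), among them the nucleolar proteins Gnl3 (0.70), Dkc1 (0.69) and Nop56 (0.72). That call held with an estimated correlation (adjusted p = 0.048). Of 68 cytosolic ribosomal protein and elongation factor genes, 42 rose and 26 did not pass (45 adjusted over the list alone), for example Eef1g (0.50), Rps23 (0.36) and Rpl4 (0.35). Their camera adjusted p was 9.1e-10, and the adjusted p = 0.44 with an estimated correlation. Among 40 cell cycle genes, 25 rose and 15 did not pass (28 adjusted over the list alone), including Ccne1 (0.83), cyclin E1, Ube2c (0.43) and the centromeric histone Cenpa (0.37). The camera adjusted p was 6.2e-08 and the adjusted p = 0.44 with an estimated correlation.

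Lists of stress responses and neural markers were higher as well. The amino acid response genes of ATF4 had 20 of 30 members higher and 3 lower (20 and 4 adjusted over the list alone, camera adjusted p = 2e-05, adjusted p = 0.22 with an estimated correlation). Sesn2 (0.80), a stress-induced mTORC1 inhibitor, Mthfd2 (0.69), a mitochondrial folate enzyme, and Slc7a5 (0.60), a leucine transporter, rose. Of 22 NRF2 antioxidant genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.52 with an estimated correlation). Gclc (0.42), Txn1 (0.36) and Txnrd1 (0.26) were higher. Of 8 neural markers, 3 rose and 5 did not pass (3 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.22 with an estimated correlation), namely Nefl, Stmn2 (1.23) and Tubb3 (0.84), which encode cytoskeletal proteins of neurons.

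Targets of FoxO factors went down, with 13 of 21 lower and 1 higher, counts that stayed at 13 and 1 adjusted over the list alone. The camera adjusted p was 0.00013, and the call held with an estimated correlation (adjusted p = 0.048). Sesn3 (−0.56), Pik3ip1 (−0.44), an inhibitor of PI3 kinase, and Foxo4 (−0.39) fell, and 53.8% of the 13 that fell carried GAAATGT. Of 15 circadian genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.22 with an estimated correlation). Tef (−0.62), Bhlhe41 (−0.49) and Per3 (−0.47) were lower, and 25% of those that fell carried GAAATGT. NF-kB inflammatory genes had 7 of 16 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.17 with an estimated correlation). The chemokines Ccl7 (−1.37) and Ccl2 (−0.74) fell, Ptgs2 (0.61), a prostaglandin synthase, rose, and 42.9% of those that fell carried the word. Interferon response genes had 8 of 25 lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.52 with an estimated correlation). Parp14 (−1.03), Gbp2 (−0.61) and Ddx58 (−0.37) were lower, and 12.5% of those that fell carried the word. The autophagy and lysosome list was only marginally lower (13 of 41 fell, 4 rose, the same adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.52 with an estimated correlation). Naglu (−0.75), a lysosomal hydrolase, fell, Atg9b (1.12) and the protease Ctsl (0.51) rose, and 7.7% of those that fell carried the word.

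Leaving out Luc ethanol library 1 ended the calls of the autophagy, interferon and NF-kB lists. The autophagy call also ended without Crebl2 ethanol library 1 or with RLE scaling, and the interferon call without Crebl2 ethanol library 2 or 3.

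The next question was how rapamycin changes control cells. Fmod, the collagen-binding proteoglycan fibromodulin, rose 4.62-fold from 66.7 ± 5.15 to 308 ± 25.5 CPM (2.21, SE 0.10, edgeR adjusted p = 1.5e-10). Mfsd2a, a transporter of lysophosphatidylcholine, fell 7.68-fold from 16.7 ± 0.738 to 2.19 ± 0.432 CPM (−2.94, SE 0.12, edgeR adjusted p = 1.2e-10). E2f2, a transcription factor of S-phase entry, fell 5.85-fold from 67.9 ± 5.06 to 11.6 ± 0.549 CPM (−2.55, SE 0.10, edgeR adjusted p = 9.1e-11), and Tfrc, the transferrin receptor (70.1% countable), fell 5.16-fold (−2.37, SE 0.12).

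In all, 2581 genes rose and 2860 fell, or 41.1% of those tested, and 233 rose and 530 fell at least 2-fold. Further large rises were Plxna4 (2.17, SE 0.18), a semaphorin co-receptor, Edn1 (1.95, SE 0.09), the peptide endothelin, and Prelp (1.88, SE 0.10), a matrix proteoglycan. They were followed by Frat2 (1.87, SE 0.15), an inhibitor of GSK3, Pim1 (1.86, SE 0.07), a survival kinase, Smoc2 (1.80, SE 0.09), a matricellular protein, and Krt14 (1.77, SE 0.08), a keratin. Further large falls were Sprr1a (−2.39, SE 0.13), Itga4 (−2.32, SE 0.11), an integrin chain, Actc1 (−2.13, SE 0.11), Gsta1 (−2.12, SE 0.10), a glutathione transferase, and Lrp8 (−1.99, SE 0.14; 26.4% countable), a lipoprotein receptor. Fmod, Mfsd2a and E2f2 lie on chromosomes 1 (134037254 to 134048277), 4 (122946850 to 122961188) and 4 (136172394 to 136196057).

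Cell cycle genes fell almost without exception: 39 of 40 were lower and all 40 were when adjusted over the list alone (median log2 fold change −1.43, camera adjusted p = 2.1e-28, adjusted p = 0.054 with an estimated correlation). Rrm2 (−1.59), the small subunit of ribonucleotide reductase, Ube2c (−1.49), a ubiquitin ligase partner of mitosis, and Ccnb2 (−1.24), cyclin B2, were among them. Cholesterol synthesis genes fell too, 22 of 25 with 3 that did not pass and 23 adjusted over the list alone, with Acat2 (−1.33), Lss (−0.88) and Hmgcs1 (−0.81) as examples. The camera adjusted p was 1.9e-13, and the call held with an estimated correlation (adjusted p = 0.047). Fatty acid synthesis genes had 11 of 19 lower and 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 0.00042, adjusted p = 0.083 with an estimated correlation), among them the elongase Elovl6 (−1.22) and the desaturases Fads2 (−0.92) and Scd2 (−0.61).

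Glycolysis, TCA cycle and oxidative phosphorylation lists were lower as well. Of 20 glycolysis genes, 16 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 4.2e-07, adjusted p = 0.12 with an estimated correlation). Pfkl (−1.02), Tpi1 (−1.0) and Pgam1 (−0.91) were lower. Of 25 TCA cycle genes, 17 fell and 1 rose (17 and 1 adjusted over the list alone, camera adjusted p = 0.00054, adjusted p = 0.29 with an estimated correlation). The dehydrogenase subunits Idh3a (−0.90) and Sdhd (−0.53) were lower. Of 62 nuclear genes of oxidative phosphorylation, 29 fell, 2 rose and 31 did not pass (30 and 2 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.42 with an estimated correlation). Cytochrome c, Cycs (−0.86), and the ATP synthase subunit Atp5f1 (−0.38) were lower.

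Amino acid response genes of ATF4 fell in 23 of 30 cases and rose in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 2e-10, adjusted p = 0.054 with an estimated correlation). Mthfd2 (−1.79), Psat1 (−1.78), an enzyme of serine synthesis, and Slc7a5 (−1.55) fell. Endoplasmic reticulum chaperone genes fell in 15 of 19 cases (15 lower and 1 higher adjusted over the list alone, camera adjusted p = 5.4e-07), for example Hsp90b1 (−0.80), Pdia3 (−0.46) and Edem1 (−0.35), a call that held with an estimated correlation (adjusted p = 0.042). HIF1 hypoxia genes fell in 12 of 17 cases and rose in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00016). Ddit4 (−1.12), Higd1a (−0.99) and the glucose transporter Slc2a1 (−0.77) were lower. The list call held as well with an estimated correlation (adjusted p = 0.042), although that estimate was −0.022, below the preset 0.01. NRF2 antioxidant genes had 13 of 22 lower and 4 higher (13 and 4 adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.42 with an estimated correlation). Gsta4 (−0.82) and Nqo1 (−0.57) were lower.

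Ribosome biogenesis genes fell, 40 of 53 with 3 that rose (43 and 3 adjusted over the list alone, camera adjusted p = 4.5e-10, adjusted p = 0.083 with an estimated correlation), among them Gnl3 (−0.87), Nop56 (−0.80) and Dkc1 (−0.71). Ribosomal protein and elongation factor genes rose, 48 of 68 with 3 that fell (50 and 3 adjusted over the list alone, camera adjusted p = 4.6e-13, adjusted p = 0.22 with an estimated correlation), among them Eef2 (0.91), Rpl3 (0.61) and Eef1a1 (0.57). The median over the 41 members of that list with at least 90% countable bases was 0.41, and over the 27 others 0.13. Muscle differentiation genes fell, 18 of 21 with 3 that did not pass (19 adjusted over the list alone, median log2 fold change −1.34, camera adjusted p = 3.1e-12, adjusted p = 0.072 with an estimated correlation), with Myom2 (−1.53) and Actn3 (−1.18), an actinin of fast fibres, among them. Extracellular matrix genes had 18 of 33 higher and 6 lower (18 and 7 adjusted over the list alone, camera adjusted p = 0.00042, adjusted p = 0.29 with an estimated correlation). Tagln (1.12), Timp3 (0.90) and Bgn (0.67) were higher. FoxO targets had 10 of 21 higher and 6 lower (11 and 6 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.11 with an estimated correlation). The muscle ubiquitin ligase Fbxo32 (0.87), Irs2 (0.86) and Pik3ip1 (0.71) were higher.

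**Figure D2:**
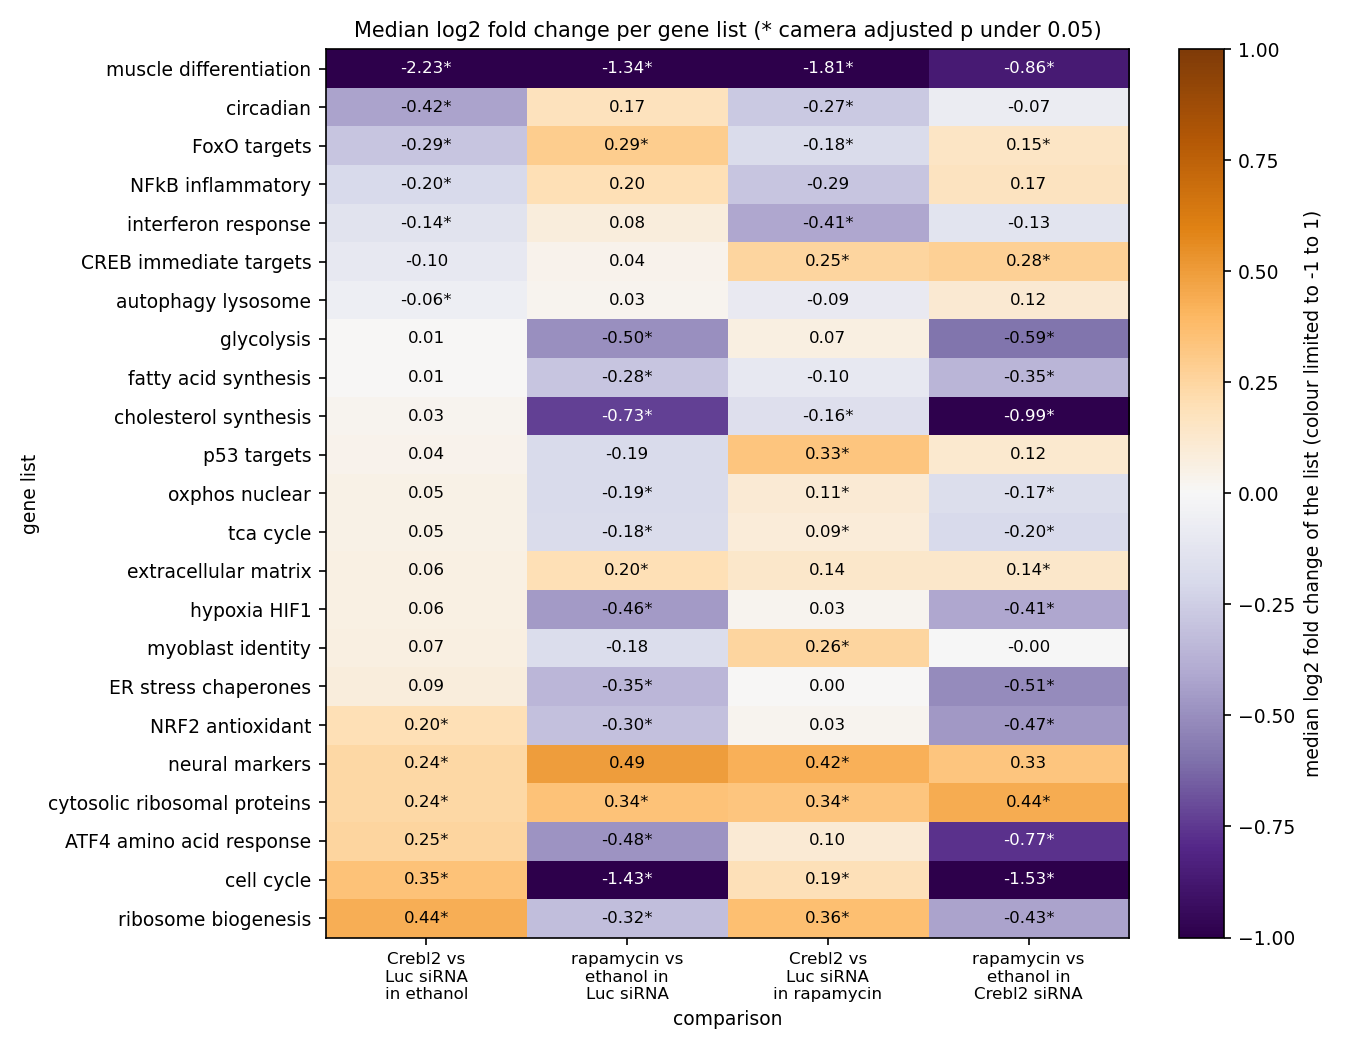
Median log2 fold change (colour, limited to −1 to 1, and printed value) in the 4 pairwise comparisons (horizontal axis). The gene lists (vertical axis) are those with a camera adjusted p under 0.05 in any of the 4 comparisons. Stars mark a camera adjusted p under 0.05, and medians carry no error bars. The cell cycle list stood at 0.35 with the Crebl2 siRNA in ethanol and at −1.43 with rapamycin in the Luc siRNA.

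The effect of the Crebl2 siRNA was measured again in cells that also received rapamycin. Stc1 rose 9.58-fold from 2.43 ± 0.709 to 23.2 ± 7.04 CPM (3.26, SE 0.23, edgeR adjusted p = 5.2e-08). Nefl rose 6.58-fold (2.72, SE 0.10), Pappa 6.34-fold (2.66, SE 0.11), and Gzme (2.45, SE 0.17), a granzyme, rose as well. Myog fell 8.33-fold to 8.97 ± 2.48 CPM (−3.06, SE 0.17, edgeR adjusted p = 3.3e-09), and Hfe2 (−2.67, SE 0.20), Actc1 (−2.26, SE 0.14) and Ifi27l2a (−2.21, SE 0.16) fell.

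In all, 2157 genes rose and 2228 fell, or 33.1% of those tested, and 184 rose and 289 fell at least 2-fold. With RLE scaling 56.2% of the calls were rises, against 49.2% with TMM. Ribosome biogenesis genes rose in 44 of 53 cases and fell in 1 (44 and 1 adjusted over the list alone, camera adjusted p = 1.3e-17, adjusted p = 0.068 with an estimated correlation). Nhp2 (0.75), Nop56 (0.59) and Gnl3 (0.57) were higher. Ribosomal protein and elongation factor genes rose in 48 of 68 cases and 20 did not pass (51 rose adjusted over the list alone, camera adjusted p = 1.3e-17, adjusted p = 0.23 with an estimated correlation). Eef1g (0.60), Rps25 (0.44) and Rpl4 (0.38) were higher. Cell cycle genes rose in 16 of 40 cases and 24 did not pass (17 rose adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.47 with an estimated correlation). Ccne1 (0.84), the helicase subunit Mcm7 (0.58) and Ube2c (0.39) were higher.

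Muscle differentiation genes fell in 15 of 21 cases and rose in 2 (15 and 3 adjusted over the list alone, median log2 fold change −1.81, camera adjusted p = 1.2e-05, adjusted p = 0.24 with an estimated correlation), with Myom2 (−1.62) lower beside Myog and Actc1. Of those that fell, 6.7% carried GAAATGT. Myoblast identity genes rose in 12 of 21 cases and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 7.9e-05, adjusted p = 0.14 with an estimated correlation), among them Hes1 (1.0), a Notch target, Msc (0.89), a repressor of MyoD activity, and Vcam1 (0.44), an adhesion protein. Neural markers rose in 4 of 8 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.22 with an estimated correlation). Stmn2 (1.26) and Tubb3 (0.59) were higher. Targets of p53 rose in 12 of 22 cases and fell in 5 (14 and 5 adjusted over the list alone, camera adjusted p = 0.00068, adjusted p = 0.068 with an estimated correlation). Sesn2 (0.72), Cdkn1a (0.56), the cell cycle inhibitor p21, and Plk2 (0.51) were higher. Immediate targets of CREB rose in 8 of 18 cases and fell in 3 (10 and 4 adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.46 with an estimated correlation). Areg (2.29), the nuclear receptor Nr4a1 (0.65) and the kinase Sik1 (0.39) were higher.

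Mitochondrial lists rose slightly. Of 62 oxidative phosphorylation genes, 20 rose and 4 fell (20 and 4 adjusted over the list alone, camera adjusted p = 0.009, adjusted p = 0.57 with an estimated correlation). Cycs (0.46) and Atp5b (0.28) were higher and Ndufb2 (−0.91) lower. Of 25 TCA cycle genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.5 with an estimated correlation). Idh3a (0.40), Cs (0.29) and Sdhb (0.27) were higher. Cholesterol synthesis genes had 14 of 25 lower and 3 higher (14 and 3 adjusted over the list alone, camera adjusted p = 0.0097, adjusted p = 0.39 with an estimated correlation). Insig1 (−0.51) and Lss (−0.43) were lower, and 35.7% of those that fell carried GAAATGT. Interferon response genes had 11 of 25 lower and 14 that did not pass (13 lower adjusted over the list alone, camera adjusted p = 0.0097, adjusted p = 0.31 with an estimated correlation). Parp14 (−0.95), Ddx58 (−0.41) and Ifit2 (−0.28) were lower, and 27.3% of those that fell carried the word. FoxO targets had 11 of 21 lower and 1 higher (12 and 1 adjusted over the list alone, camera adjusted p = 0.0068, adjusted p = 0.084 with an estimated correlation). Sesn3 (−0.83), Cdkn1b (−0.63), the inhibitor p27, and Foxo4 (−0.36) were lower, and 54.5% of those that fell carried the word. Circadian genes had 10 of 15 lower and 5 that did not pass (10 adjusted over the list alone, camera adjusted p = 0.00026, adjusted p = 0.084 with an estimated correlation). Per2 (−0.69), Tef (−0.60) and Per3 (−0.52) were lower, and 3 of the 10 that fell carried the word.

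The call of the CREB targets ended with RLE scaling and without Luc rapamycin library 1 or 3 or Crebl2 rapamycin library 2, whose omission also ended the TCA cycle call. The effects of the Crebl2 siRNA in ethanol and in rapamycin, which share no library, correlated across genes with r = 0.749 and rho = 0.689, where genes are not independent replicates. Of the genes called in ethanol, 94.2% moved in the same direction in rapamycin and 62.4% were also called that way. Both contrasts raised 1678 genes and lowered 1495, against 462 and 378 for independent lists.

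A sequence word was more frequent among the genes that the Crebl2 siRNA lowered, although most of them lacked it. Among 16333 words of 7 bases found in the 3' UTRs of at least 20 genes, GAAATGT, present in 1772 of 8849 genes, went with lower log2 fold changes for the Crebl2 siRNA in ethanol (z = −8.95) and in rapamycin (z = −10.29), and not for rapamycin with the Luc siRNA (z = 0.35) or the Crebl2 siRNA (z = −0.37). The lowest z of any word after a single permutation of the changes in ethanol was −4.08. The word occurs in the coding part of the Crebl2 transcript, at positions 484 to 490 of 3629, across the junction of exons 2 and 3. Of genes with the word, 21% were called lower in both siRNA contrasts, against 12.7% of genes without it (2-sided Fisher's exact p = 7.5e-18, across genes, which are not independent replicates). The word was chosen from these same contrasts, so this p is no separate test. These shares were not adjusted for UTR length or GC content. The word was carried by 25.6% of the searched genes lowered in ethanol, 31.3% of those lowered in rapamycin and 29.3% of those lowered in both. Among 5229 genes called in neither, 17.9% carried it. These came from a wider set than the 8849, which also held genes of lower expression or with shorter 3' UTRs. Among the 8 largest falls in ethanol it was present in Klhl41, and in rapamycin the 4 largest falls lacked it.

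**Figure D3:**
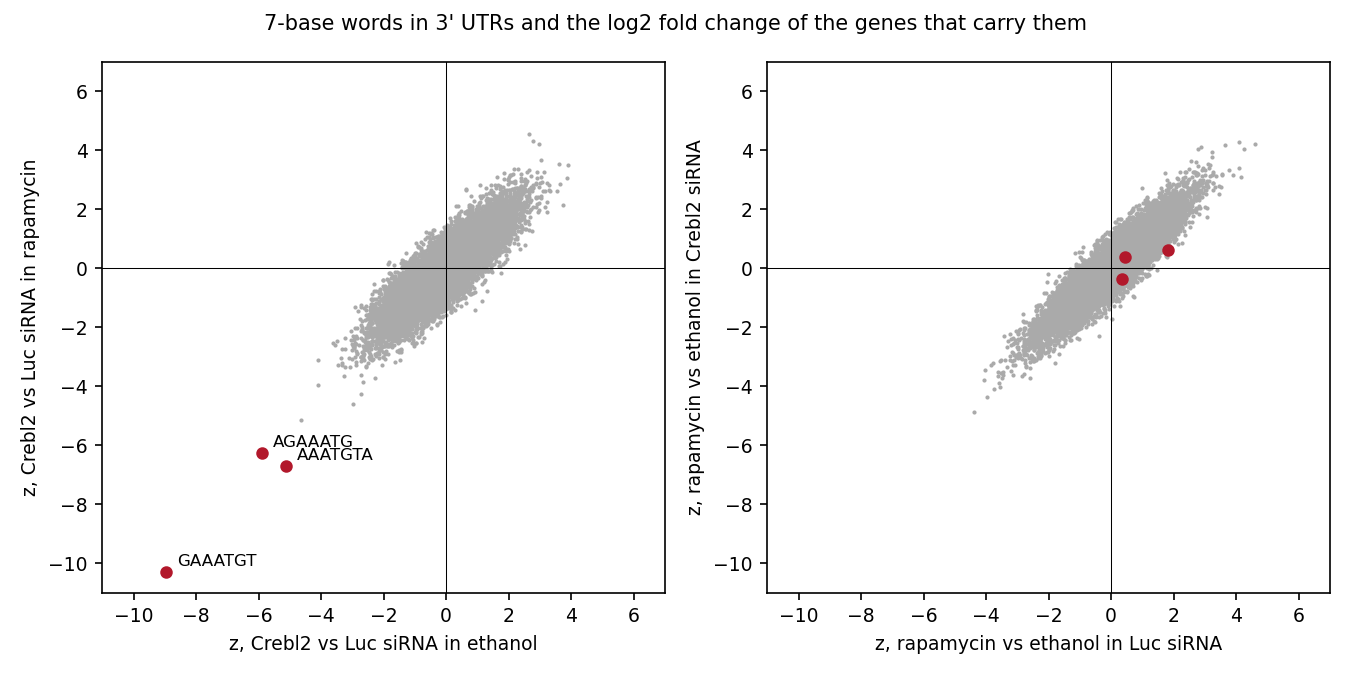
Score (z) of each 7-base word in 3' UTRs for the siRNA contrasts in ethanol and rapamycin (left axes) and for the rapamycin contrasts with each siRNA (right axes); each point is a word, with no error bars, and red points are the 3 words with the lowest scores in both siRNA contrasts. GAAATGT stood at −8.95 and −10.29 on the left.

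Rapamycin was then compared with ethanol in cells with the Crebl2 siRNA. Edn1 rose 4.58-fold from 8.22 ± 0.862 to 37.6 ± 1.65 CPM (2.20, SE 0.09, edgeR adjusted p = 3.4e-11), and Frat2 (2.03, SE 0.15), Ypel1 (1.93, SE 0.09) and Pim1 (1.92, SE 0.07) rose as well. Aldh1l2, a mitochondrial folate enzyme of which 36.4% of bases were countable, fell 6.45-fold from 12.5 ± 0.949 to 1.94 ± 0.171 CPM (−2.69, SE 0.11, edgeR adjusted p = 5.9e-11). Mfsd2a (−2.60, SE 0.11), Lrp8 (−2.28, SE 0.14; 26.4% countable) and Gsta1 (−2.27, SE 0.10) fell. In all, 2614 genes rose and 3387 fell, or 45.3% of those tested, and 333 rose and 528 fell at least 2-fold.

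Cell cycle genes fell in 38 of 40 cases (39 adjusted over the list alone, median log2 fold change −1.53, camera adjusted p = 6.5e-25, adjusted p = 0.075 with an estimated correlation). Rrm2 (−1.66), Ube2c (−1.53) and Cenpa (−1.41) were lower. Cholesterol synthesis genes fell in 21 of 25 cases and 4 did not pass (21 adjusted over the list alone, camera adjusted p = 5.3e-12, adjusted p = 0.053 with an estimated correlation). Acat2 (−1.68) and Hmgcs1 (−1.07) were lower. Fatty acid synthesis genes fell in 12 of 19 cases and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00054, adjusted p = 0.09 with an estimated correlation). Elovl6 (−1.57), Fads2 (−1.11) and Scd2 (−0.73) were lower. Glycolysis genes fell in 14 of 20 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 8.2e-06, adjusted p = 0.2 with an estimated correlation). Pfkl (−1.12), Slc2a1 (−1.01) and Pgam1 (−0.99) were lower. TCA cycle genes fell in 15 of 25 cases and rose in 2 (19 and 2 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.33 with an estimated correlation). Idh3a (−0.96), Sdhd (−0.60) and Mdh1 (−0.49) were lower. Oxidative phosphorylation genes fell in 24 of 62 cases and rose in 4 (24 and 4 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.57 with an estimated correlation). Cycs (−0.87) and Uqcrb (−0.42) were lower.

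Amino acid response genes of ATF4 had 27 of 30 members lower and 1 higher (27 and 1 adjusted over the list alone, camera adjusted p = 5.3e-12, adjusted p = 0.053 with an estimated correlation). Psat1 (−2.02), Mthfd2 (−2.0) and Slc7a5 (−1.99) were lower. Endoplasmic reticulum chaperone genes had 17 of 19 lower and 2 that did not pass (17 adjusted over the list alone, camera adjusted p = 4.9e-08), with Hsp90b1 (−1.02), Pdia3 (−0.59) and Edem1 (−0.58) lower. This was the one list call of this comparison that held with an estimated correlation (adjusted p = 0.046). NRF2 antioxidant genes had 14 of 22 lower and 2 higher (15 and 2 adjusted over the list alone, camera adjusted p = 2e-04, adjusted p = 0.27 with an estimated correlation). Gsta4 (−0.99), Gclc (−0.83) and Srxn1 (−0.67) were lower. HIF1 hypoxia genes had 11 of 17 lower and 2 higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.053 with an estimated correlation). Higd1a (−0.87) and Egln3 (−0.77) were lower. Ribosome biogenesis genes had 44 of 53 lower and 4 higher (45 and 4 adjusted over the list alone, camera adjusted p = 1.3e-11, adjusted p = 0.078 with an estimated correlation). Gnl3 (−1.01), Dkc1 (−0.97) and Nop56 (−0.93) were lower. Ribosomal protein and elongation factor genes had 48 of 68 higher and 4 lower (49 and 4 adjusted over the list alone, camera adjusted p = 3.9e-15, adjusted p = 0.21 with an estimated correlation). Eef2 (1.09), Eef1a1 (0.69) and Rpl4 (0.56) were higher.

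Muscle differentiation genes had 13 of 21 lower and 8 that did not pass (13 adjusted over the list alone, median log2 fold change −0.86, camera adjusted p = 0.0018, adjusted p = 0.33 with an estimated correlation). Mymk (−1.62; 28.5% countable), Myom2 (−1.03) and the calcium pump Atp2a1 (−0.90) were lower. Extracellular matrix genes had 16 of 33 higher and 8 lower (18 and 8 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.33 with an estimated correlation). The smooth muscle proteins Tagln (1.44) and Acta2 (0.83) and the protease inhibitor Timp3 (0.82) were higher. FoxO targets had 12 of 21 higher and 5 lower (12 and 5 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.1 with an estimated correlation). Fbxo32 (1.46), Irs2 (0.96) and Pik3ip1 (0.88) were higher. Immediate targets of CREB had 8 of 18 higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.33 with an estimated correlation). Junb (0.89), the phosphatase Dusp1 (0.66) and Nr4a1 (0.58) were higher. The oxidative phosphorylation call ended without Crebl2 ethanol library 3 or Crebl2 rapamycin library 1 or 3.

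Rapamycin changed much the same genes with either siRNA. Its effects with the Luc siRNA and with the Crebl2 siRNA, which share no library, correlated across genes with r = 0.780 and rho = 0.761. Of the genes called with the Luc siRNA, 96.3% moved in the same direction with the Crebl2 siRNA and 79.3% were called that way. Both contrasts raised 1891 genes and lowered 2424, against 509 and 731 for independent lists. Over the 7315 genes called for the mean rapamycin effect, the median response was 0.36 with the Luc siRNA and 0.42 with the Crebl2 siRNA, a ratio of 1.17 on the log2 scale.

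Many genes that the Crebl2 siRNA raised, rapamycin lowered. Of the genes called in both contrasts that share the Luc ethanol libraries, 1381 were higher with the Crebl2 siRNA and lower with rapamycin (612 for independent lists) and 784 the reverse (438), while 407 were higher in both (553) and 378 lower in both (485). Gnl3, Dkc1 and Nop56 belonged to the first of these sets, and Actc1 and Myom2 to the last. Log2 fold changes of the contrasts correlated across genes with r = −0.060 and rho = −0.197, against r = 0.486 in simulations of unchanged groups, and their covariance was −0.016 against 0.0215. The 3 shared libraries could not be divided into parts of at least 2. Their noise moves both contrasts the same way, so part of the genes higher or lower in both may come from it, and it works against opposite changes. With the rapamycin effect taken from the Crebl2 siRNA cells, which share the Crebl2 ethanol libraries with opposite sign, r was −0.331 against −0.500 in simulations and the covariance −0.0941 against −0.0226. The first correlation was positive when Luc ethanol library 2 (0.0179) or 3 (0.0438) was left out.

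The series asked what part Crebl2 plays in the changes with rapamycin, which the interaction of siRNA and treatment tests. A positive interaction marks a smaller fall or a larger rise with rapamycin in cells with the Crebl2 siRNA. Actn3 went from 179 ± 11.6 to 79.1 ± 3.71 CPM with rapamycin in the Luc siRNA and from 183 ± 11.9 to 160 ± 8.93 CPM in the Crebl2 siRNA (interaction 0.99, SE 0.09, edgeR adjusted p = 0.00012). Fos, an immediate early transcription factor, went from 26.7 ± 1.52 to 20.0 ± 2.72 CPM in the Luc siRNA and from 17.0 ± 0.998 to 26.0 ± 1.96 CPM in the Crebl2 siRNA (1.03, SE 0.13, edgeR adjusted p = 0.001). Trib3, a pseudokinase induced by ATF4, went from 6.56 ± 0.642 to 4.70 ± 0.156 CPM and from 10.7 ± 0.397 to 3.99 ± 0.264 CPM (−0.94, SE 0.14, edgeR adjusted p = 0.003).

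The interaction was called for 159 genes, or 1.2% of those tested, 81 positive and 78 negative. These counts depended on the processing: DESeq2 called 186 and 191, a replicate block 91 in all, and fits without 1 library 56 to 136 positive and 18 to 63 negative. The positive count was 136 without Luc rapamycin library 2. The negative count was 38 without Luc ethanol library 2, 24, 36 and 18 without Luc rapamycin libraries 1, 2 and 3, 46 without Crebl2 ethanol library 1, and 26, 32 and 18 without Crebl2 rapamycin libraries 1, 2 and 3. With RLE scaling 64.5% of the calls were positive, against 50.9% with TMM. The other leading positive genes were Actc1 (1.27, SE 0.19), Acta1 (1.13, SE 0.16) and Tmod1 (1.04, SE 0.16), which caps actin filaments. The other leading negative genes were Aldh1l2 (−0.94, SE 0.16; 36.4% countable), Fmod (−0.91, SE 0.13) and Tent5c (−0.80, SE 0.15), a poly(A) polymerase.

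**Figure D4:**
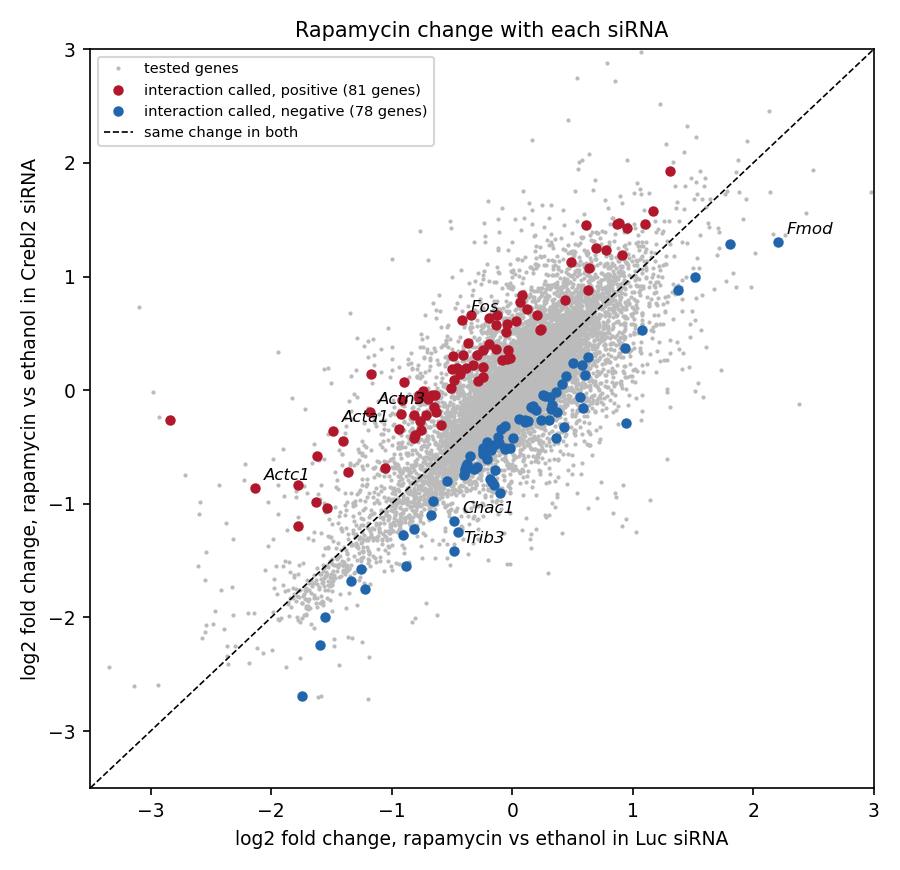
Log2 fold change of 13247 tested genes with rapamycin in the Luc siRNA (horizontal axis) and in the Crebl2 siRNA (vertical axis); red and blue points mark the 81 positive and 78 negative interactions, the dashed line marks equal change, and points carry no error bars. Actc1, Acta1 and Actn3 lie above the line and Fmod, Trib3 and Chac1 below it, and 5 genes lie outside the axes.

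Of 21 muscle differentiation genes, 6 had a positive interaction and 15 did not pass (8 positive adjusted over the list alone, median 0.42, camera adjusted p = 2e-11, adjusted p = 0.11 with an estimated correlation), with Actc1, Acta1 and Actn3 leading. In the Crebl2 siRNA cells given rapamycin the median count of all 21 members was 120.7, and that of the 6 was 869.7. Of 22 targets of p53, 5 had a positive interaction and 17 did not pass (7 positive adjusted over the list alone, camera adjusted p = 1.1e-05), with Pmaip1 (0.68), which promotes apoptosis, and Btg2 (0.62) and Cdkn1a (0.58), which restrain division. This was the one list call of the interaction that held with an estimated correlation (adjusted p = 0.019). Of 21 myoblast identity genes, 5 had a positive interaction (8 positive and 1 negative adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.11 with an estimated correlation), with the Notch targets Hes1 (0.73), Hey1 (0.64) and Heyl (0.58). Of 18 immediate targets of CREB, 3 had a positive interaction, namely Fos, Nr4a1 (0.71) and Dusp1 (0.46) (4 positive adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.14 with an estimated correlation). Of 9 targets of MondoA and Mlx, which sense glucose phosphates, Rgs16 (0.62) was called and 8 did not pass (2 positive adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.14 with an estimated correlation). The listed target Txnip had almost no counts and was not among these 9.

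On the negative side, 4 of 30 amino acid response genes of ATF4 were called (7 adjusted over the list alone, camera adjusted p = 1e-04, adjusted p = 0.23 with an estimated correlation), among them Trib3, Chac1 (−0.67), which degrades glutathione, and Slc7a5 (−0.44). Of 25 cholesterol synthesis genes, 3 were called, among them Msmo1 (−0.40) and Acat2 (−0.35). The other 22 did not pass (10 negative and 1 positive adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.29 with an estimated correlation). Of 22 NRF2 antioxidant genes, G6pdx (−0.46), which makes NADPH, and Srxn1 (−0.28) were called and 20 did not pass (4 negative adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.34 with an estimated correlation). Of 19 endoplasmic reticulum chaperone genes, Edem1 (−0.23) was called and 18 did not pass (5 negative adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.11 with an estimated correlation).

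A further 4 lists were called by camera with no single member called by edgeR, over all genes or adjusted over the list alone. Camera compares a list with the other genes, and the median interaction over all 13247 tested genes was −0.033 (−0.009 with RLE scaling). At an unadjusted edgeR p under 0.05, 1892 of all tested genes were positive or negative. Ribosomal protein genes had a median interaction of 0.07 (camera adjusted p = 6.5e-05, adjusted p = 0.5 with an estimated correlation). At an unadjusted p under 0.05, 4 of 68 were positive, and DESeq2 called 1. Ribosome biogenesis genes had a median of −0.11 (camera adjusted p = 0.00019, adjusted p = 0.34 with an estimated correlation). At an unadjusted p under 0.05, 12 of 53 were negative, and DESeq2 called 1. Oxidative phosphorylation genes had a median of 0.03 (camera adjusted p = 0.024, adjusted p = 0.68 with an estimated correlation). At an unadjusted p under 0.05, 3 of 62 were positive, and DESeq2 called 1. Cell cycle genes had a median of −0.10 (camera adjusted p = 0.031, adjusted p = 0.7 with an estimated correlation). At an unadjusted p under 0.05, 6 of 40 were negative, and DESeq2 called 0.

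Of the named genes with a called interaction, 21 kept the call in every fit without 1 library, while Acat2 and Edem1 lost it in all 12, Cx3cl1 and Srxn1 in 11, Msmo1 and Rgs16 in 8, Lox and Tent5c in 4, Col6a1 in 3 and Hes1 in 2. The MondoA call ended without Luc ethanol library 2 and the ribosome biogenesis call without Crebl2 rapamycin library 1. The oxidative phosphorylation call ended without Luc ethanol library 1, Crebl2 ethanol library 2 or Crebl2 rapamycin library 2. The cell cycle call ended without Luc ethanol library 1 or 2, Luc rapamycin library 1 or 3, Crebl2 ethanol library 1 or Crebl2 rapamycin library 1 or 3.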

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

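The tests of residual counts in the muscle list and of overlapping transcripts in the ribosomal list were chosen only after their results were seen. The results in the next 2 paragraphs and the counts here were raised because the change with rapamycin differed between the siRNAs, tested by the interaction term of edgeR for genes and by camera for lists. The 3 patterns weighed after them include 2 that are not interactions. Positive interactions were called for 81 genes and negative ones for 78. Of 100 splits that redrew the treatment labels within each siRNA, the real one included, 3 called at least as many genes as the real 159. Such splits mix rapamycin and ethanol libraries in a group, where the rapamycin effect widens the spread, so they do not show whether chance is excluded. The highest other split called 3525 and the next 1648; in both of these, 2 of the 3 Luc libraries of each treatment had traded labels while the Crebl2 labels stayed in place. The 5 splits that traded 2 of the 3 Crebl2 libraries of each treatment and left the Luc labels in place called 9 to 46 genes. Trading labels in only the Luc or only the Crebl2 siRNA puts part of the rapamycin effect itself into the interaction contrast. Such counts therefore do not measure chance. Why the Luc trades called more genes than the Crebl2 trades was not tested.

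Lists with a called interaction had a median of 0.42 for muscle differentiation, 0.22 for CREB immediate targets, 0.13 for p53 targets, 0.12 for myoblast identity, 0.08 for MondoA targets, 0.07 for ribosomal proteins and 0.03 for oxidative phosphorylation. Negative medians were −0.18 for cholesterol synthesis, −0.16 for NRF2 genes, −0.14 for ATF4 genes, −0.12 for chaperones, −0.11 for ribosome biogenesis and −0.10 for the cell cycle. The median over all tested genes was −0.033. With an estimated correlation in camera, 12 of these 13 calls were lost and that of p53 targets was kept.

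Named genes with a positive interaction on the log2 scale were Actc1 (1.27), Acta1 (1.13), Tmod1 (1.04), Fos (1.03), Actn3 (0.99), Hes1 (0.73), Nr4a1 (0.71), Pmaip1 (0.68), Hey1 (0.64), Rgs16 (0.62), Btg2 (0.62), Fbxo32 (0.59), Hist1h1c (0.59), Heyl (0.58), Cdkn1a (0.58) and Dusp1 (0.46). Those with a negative one were Aldh1l2 (−0.94), Trib3 (−0.94), Fmod (−0.91), Tent5c (−0.80), Chac1 (−0.67), Slc16a1 (−0.60), Lox (−0.47), G6pdx (−0.46), Slc7a5 (−0.44), Msmo1 (−0.40), Col6a1 (−0.40), Acat2 (−0.35), Cx3cl1 (−0.34), Srxn1 (−0.28) and Edem1 (−0.23). Without 1 library, Acat2 and Edem1 lost the call in all 12 fits, Cx3cl1 and Srxn1 in 11, Msmo1 and Rgs16 in 8, Lox and Tent5c in 4, Col6a1 in 3 and Hes1 in 2, with a highest edgeR adjusted p of 0.052 for Hes1 to 0.33 for Edem1.

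Genes lower with the Crebl2 siRNA in both ethanol and rapamycin form the first pattern. A candidate explanation for part of it is off-target silencing by the siRNA seed. GAAATGT had a z of −8.95 in ethanol and −10.29 in rapamycin, and no other word went below −6 in both. It lies in the Crebl2 transcript, as does AGAGATC, which went with higher changes (z = 3.9 and 3.5), so occurrence there says little. The siRNA sequence was not given in the labels, so a match of GAAATGT with it was not checked. Genes with the word that were lower in both exceeded the share without it by 148, of 1272 genes lower in both. That excess was not adjusted for UTR length or GC content, and the word was chosen from these same contrasts. For the muscle differentiation list the word argues little, since 6.2% of its members that fell carried it (95% exact interval 0.2 to 30.2%), against 17.9% of genes called in neither contrast. The median of members without the word was −2.23. Among FoxO targets, 53.8% of the 13 that fell in ethanol carried it (25.1 to 80.8%) and 6 fell without it. The median of members without it was −0.24, against −0.29 for all, so off-target silencing stays open for those with the word. A seed match in an upstream regulator stays open as a cause, and with 1 siRNA sequence against Crebl2 the loss of the gene remains the untested biological explanation.

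The second pattern is the positive interaction of the muscle differentiation list, with 6 of 21 members called, 15 that did not pass and a list call lost with an estimated correlation (camera adjusted p = 2e-11, adjusted p = 0.11). A floor of residual counts cannot be told apart from it over the whole list, because the median count was 120.7 in the Crebl2 siRNA libraries with rapamycin, with a bootstrap range of 7.3 to 355.3 and 8 of 21 members under 10 reads. The 6 members called by the interaction were Actn3, Chrna1, Myom2, Acta1, Actc1 and Tnnc1, of which Chrna1, Myom2 and Tnnc1 were named after their values were seen. Their median count was 869.7 and their lowest 120.7, for Actc1, which argues against such a floor for these 6. A call needs enough reads, so this does not extend to the other members. A general weakening of the response is argued against by 7296 other genes called for the mean rapamycin effect, whose median interaction in the direction of that effect was 0.061 (0.056 to 0.065), against −0.427 (−0.804 to −0.287) for 18 list members. What stays open is a low level of muscle genes from which rapamycin may have little left to lower. That does not apply to Actn3, which stood at 179 and 183 CPM in ethanol with the Luc and the Crebl2 siRNA and at 79.1 and 160 CPM in rapamycin. Also open is Crebl2 dependence, as a hypothesis.

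Ribosomal protein genes, higher with the Crebl2 siRNA and with rapamycin, form the third pattern. A trend with transcript length is argued against by 10000 random lists matched on length and expression, whose medians were 0.05 (−0.02 to 0.11) against 0.24 for the siRNA in ethanol and −0.01 (−0.09 to 0.09) against 0.34 for rapamycin, although matching was imperfect (median CPM 426 against 960.8). Reads of overlapping transcripts are argued against by the 41 members with at least 90% countable bases, whose medians were 0.25 (0.22 to 0.28) and 0.41 (0.35 to 0.43). Reads shared with processed pseudogenes, which lie elsewhere and are not measured by that share, cannot be told apart from a regulated rise of these transcripts, so the cause stays open.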

How the results depend on the processing

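Tests of single transcripts and of genes with at least 90% countable bases were chosen only after the data had been seen. Counts of called genes in the 4 pairwise contrasts stayed within 1.5 times their value under all alternatives. Of 5977 values of named genes under alternatives, 5821 kept their side of the threshold, 118 lost and 38 gained a call. No named gene called in the main fit turned direction, while turns of uncalled genes were not counted.

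The interaction depended most on the processing. Its 81 positive calls became 310 with no filter, 186 with DESeq2, 136 with single transcripts and 56 to 136 with 1 library left out (136 without Luc rapamycin library 2). Its 78 negative calls became 49 with RLE scaling, 191 with DESeq2, 35 with single transcripts and 18 to 63 with 1 library left out. They numbered 38 without Luc ethanol library 2, 24, 36 and 18 without Luc rapamycin libraries 1, 2 and 3, 46 without Crebl2 ethanol library 1, and 26, 32 and 18 without Crebl2 rapamycin libraries 1, 2 and 3. More genes were tested with no filter. Each omission left fewer libraries, and the filter was applied again, so the tested genes could differ there too. Otherwise the cause was not tested.

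A replicate block gave 36 negative calls and 91 interaction calls in all, 88 of them among the 159. Same-numbered libraries deviated with correlations of −0.292 to 0.11, and differently numbered ones with −0.315 to 0.374. Such deviations from group means neither show nor exclude that same-numbered libraries share a day or batch. The block ended 7 calls of named genes, among them the interaction calls of Acat2, Cx3cl1, Edem1, Rgs16 and Srxn1 and the call of Bmp4 with the Crebl2 siRNA in ethanol, and changed no other count by over 1.5 times.

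With an estimated correlation in camera, the lists higher and lower went from 6 and 6 to 1 and 1 for the Crebl2 siRNA in ethanol, from 3 and 12 to 0 and 3 for rapamycin with the Luc siRNA, from 9 and 5 to 0 and 0 for the Crebl2 siRNA in rapamycin, from 4 and 12 to 0 and 1 for rapamycin with the Crebl2 siRNA, and from 7 and 6 to 1 and 0 for the interaction. With fry, which does not compare lists with other genes, 13 lists were higher for the Crebl2 siRNA in ethanol, 10 lower for it in rapamycin, and 7 and 8 higher for rapamycin with the Luc and the Crebl2 siRNA. With 1 library left out, the lists higher and lower ranged over 6 to 7 and 3 to 6 (3 without Luc ethanol library 1), 3 to 3 and 12 to 12, 7 to 10 and 5 to 6, 4 to 5 and 11 to 12, and 6 to 9 and 4 to 7 in the same order.

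The correlation of the siRNA effects in ethanol and rapamycin was 0.749, 0.863 at a minimum count of 50, which removes noisy low counts, and 0.666 to 0.723 with 1 library left out. That of the rapamycin effects with each siRNA was 0.780, 0.895 and 0.707 to 0.763. That of the siRNA and rapamycin effects was −0.060, −0.171 and −0.0560 to 0.0438, turning positive without Luc ethanol library 2 (0.0179) or 3 (0.0438), as did its covariance (−0.016; −0.0161 to 0.0133; 0.00524 and 0.0133). Without any 1 library, the correlations of like effects were always lower than in the full fit, and that of siRNA with rapamycin effects always higher. The count filter was applied again in each such fit, so the tested genes could differ. The cause was not tested.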

Other observations

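The tests in this part were planned before their results were seen. Some metabolic lists were not called as a whole although members moved. Of 28 fatty acid oxidation genes, 11 rose and 8 fell with rapamycin in the Crebl2 siRNA cells (camera adjusted p = 0.21), and with the Luc siRNA 9 rose and 5 fell (camera adjusted p = 0.3); there Pdk4 (0.68), which restrains pyruvate oxidation, rose and Angptl4 (−0.64), an inhibitor of lipoprotein lipase, fell. With the Crebl2 siRNA in ethanol 3 rose and 5 fell (camera adjusted p = 0.54), among them Echs1 (−0.28). Of 12 glycogen metabolism genes, 5 rose and 2 fell with rapamycin in the Luc siRNA (camera adjusted p = 0.5), among them Epm2a (0.60) and Phkb (0.35). Of 10 pentose phosphate genes, 4 rose and 1 fell with the Crebl2 siRNA in ethanol (camera adjusted p = 0.5), among them Prps1 (0.56) and G6pdx (0.30), and 5 fell and 1 rose with rapamycin in those cells (camera adjusted p = 0.16). Of 27 insulin, IGF and mTOR signalling genes, 12 fell and 6 rose with rapamycin in the Crebl2 siRNA cells (camera adjusted p = 0.45), and with the siRNA in ethanol 8 rose and 7 fell (camera adjusted p = 0.73), among them Igfbp3 (0.50) and Slc2a1 (0.39). MondoA targets were called in none of the 4 pairwise contrasts, where Klf10 (0.48) and Rgs16 (0.58) rose with the Crebl2 siRNA in ethanol and Hbp1 (0.66) rose with rapamycin in the Luc siRNA. Only 9 of the 14 listed targets were tested, and the listed target Txnip, which had almost no counts, was not among them.

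Relatives and partners of Crebl2 went both ways. Of 20 CREB and ATF family genes, 6 rose and 5 fell with the Crebl2 siRNA in ethanol (camera adjusted p = 0.73), among them Crebl2 itself, the siRNA target, and Crtc1 (−0.43), a CREB co-activator. Of the 5 that fell, 4 (80%) carried GAAATGT in their 3' UTR, Crtc1 among them and Crebl2 not. Off-target silencing stays open for these 4. With rapamycin in the Luc siRNA 7 rose and 3 fell (camera adjusted p = 0.48); Crebrf (1.05), which degrades CREB3, rose and Atf4 (−0.68) fell. Of 11 histone genes, 4 rose and 1 fell with the Crebl2 siRNA in ethanol (median 0.64; camera adjusted p = 0.14). Of 8 osteoblast markers, 3 rose and 2 fell with rapamycin in the Luc siRNA (camera adjusted p = 0.51), among them Bmp4 (0.88) and Dmp1 (−1.27). Lists with under 5 tested members were not tested: of 4 adipocyte markers 1 rose and 2 fell with the Crebl2 siRNA in ethanol, of 4 leukocyte markers 2 fell, of 2 epithelial and liver markers 1 rose and 1 fell, and of 4 RNA polymerase III and nuclear RNA genes 2 fell. The single endothelial marker tested rose with rapamycin, and no mitochondrially encoded gene was counted.

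For the pairwise contrasts, 3 libraries against 3 give 10 splits, too few for a share under 0.05. Fitted alone, the real split was the 1 with the most calls in each: 4528 genes for the Crebl2 siRNA in ethanol, 5231 for rapamycin with the Luc siRNA, 4406 for the Crebl2 siRNA in rapamycin and 5951 for rapamycin with the Crebl2 siRNA. The highest of the other splits called 0 genes with edgeR in all 4. Those splits mix the compared groups, and the effect itself then widens the spread, so their 0 calls do not show that chance is excluded.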
